A study of Mus musculus with 8 samples.

How the data were processed

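The series holds 8 libraries of mouse colon, 1 per mouse, 4 from mice fed corn oil with cellulose and 4 from mice fed fish oil with pectin. Per the labels' protocols, 2 sections of 50 µm were cut from paraffin-embedded colon rolls and processed with the 10x Genomics fixed RNA profiling kit for multiplexed samples. Per the file headers and the submitters' processing notes, Cell Ranger 8.0.0 made the deposited matrices, and the notes name the builds mm10 and GRCm39. The deposited values are raw UMI counts per gene and called cell barcode, with no normalization, for 19065 genes. Whether barcodes were filtered further is not stated in the labels. The files pair gene IDs with symbols and hold no coordinates; loci were looked up by ID in the GRCm38 annotation.

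Depth ran from 34758 to 245476 UMIs and from 106 to 5180 barcodes per library, 8588 barcodes and 1160832 UMIs in all. Intervals given for a count of UMIs are exact Poisson intervals at 95% and cover counting error only. No 2 libraries were copies of one another: chi-square per degree of freedom between libraries was at least 3.40 over 28 pairs. Barcodes of this kit join a droplet barcode of 16 bases and a sample barcode of 8 bases. Libraries run in the same pool share droplets, and 189 droplet barcodes were shared within 2 groups of 4 libraries where 9.38 would be expected, against 24 where 20.9 would be expected between the groups. These groups are called pools. They hold 3 corn oil/cellulose mice with 1 fish oil/pectin mouse and the reverse, so pool and diet are partly confounded, and differences were also computed within pools and with the pool in the fit.

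The mouse was the unit of replication. Raw counts were summed over all barcodes of each mouse, and over the barcodes of a class where at least 10 barcodes per mouse in at least 3 mice per diet allowed it. Sums were compared between diets with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 5, TMM factors, robust quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05). Gene lists with at least 5 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry. In all, 37 lists had been fixed, 16 of cell type markers and 21 of pathways. Another 4 marker lists were added after the data had been seen and were not tested by camera. Shares and library measures were compared with two-sided exact permutation tests over 70 assignments. The diet difference between epithelial-like and other barcodes was tested as an interaction with the mouse as a block.

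Barcodes with at least 100 UMIs, 2632 in all, were scaled to 10000, log transformed and clustered over all mice with scanpy 1.11.5. This used 2000 variable genes, 20 principal components, 15 neighbours and Leiden clustering by igraph 0.11.9 at resolution 0.5, and gave 10 clusters. A cluster took the name of the fixed marker list with the largest share of its markers raised, at least 3 of them. Raised meant at least 10 UMIs and a log2 fold of at least 1 over other clusters. A cluster stayed unnamed, as mixed, where a list of another class had at least 3 raised at 50% or more of that share. It also stayed unnamed where another class had more markers among the 10 leading genes, or where depth was low and no marker led. Clusters with a median haemoglobin share of at least 50% were called haemoglobin-led. This naming rule uses no diet labels, but it was settled after an exploratory epithelial test of diet, which called Slc13a2, had been seen, and after the first rule had left the colonocyte-like cluster unnamed and so too few mice for the planned test. Both a first clustering in single precision and the final clustering were tried, and 3 naming procedures: reading by hand, at least 3 markers among the top 20 genes, and at least 3 raised markers.

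The comparisons, their tests, the gene lists, the rule for named genes and the first set of alternative settings were chosen before the data were examined. The rule for named genes takes up to 12 called genes per direction with the largest fold change, 8 genes of smallest p per direction where fewer than 10 pass, up to 4 members of smallest p of each list discussed, and 14 genes fixed by name, of which Gpx4 was not analysed here. Not every gene the rule picks is given in the text. Members of the goblet and antimicrobial lists in the epithelial-like sums are left unnamed. That first set held other scalings, count filters, DESeq2 1.42.0 and limma voom with quality weights, thinning, leaving out each mouse, minimum UMIs or genes per barcode, other cluster settings, Scrublet and a block by mouse number. Alternatives added after the data were seen are the pool as a covariate, leaving out haemoglobin-led or adipocyte-like barcodes or haemoglobin and mitochondrially encoded genes, the goblet-like share as a covariate, the colonocyte-like or goblet-like cluster alone, naming by the top 20 genes, the first clustering and other clustering seeds. A gene list was counted as reversed when its median or its test turned.

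The tests were tried on simulated counts drawn from the means and library sizes of these mice, with 200 genes changed in each of 10 simulations. In the all-cell sums, of 4425 to 5241 genes tested, 3.14% of genes changed by a fold of 2 were recovered, 40.9% by a fold of 4 and 91.2% by a fold of 8, and 5.51% of calls were wrong. In the epithelial-like sums, of 593 to 637 genes, the recovered shares were 21.3%, 89.6% and 100%, and 4.63% of calls were wrong. A list raised by a fold of 2 was called in 10 of 10 simulations in both. Genes were drawn independently from a shared mean profile, so correlation within lists and differences in cell mix were not simulated. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 computed the other tables, and matplotlib 3.10.9 drew the figures.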

Results

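Colon tissue from 8 C57BL/6 mice was profiled by probe-based single-cell RNA sequencing of fixed tissue, which counts RNA through pairs of gene-specific probes. In this design 4 mice had eaten corn oil with cellulose and 4 had eaten fish oil with pectin for 3 weeks, and each mouse gave 1 library from 2 sections of 50 µm of a paraffin-embedded colon roll. The series title places the question in colonocytes, the absorptive cells of the colon lining, and names ferroptosis, an iron-dependent cell death driven by lipid peroxidation. The comparison between diets therefore asks which genes and cell types differ, with lipid, iron and antioxidant genes in view.

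Corn oil/cellulose mice 1 to 4 gave 5180, 448, 106 and 527 cell barcodes with 193096, 99917, 81400 and 245476 UMIs (unique molecular identifiers, the counted RNA molecules). Fish oil/pectin mice 1 to 4 gave 290, 969, 776 and 292 barcodes with 34758, 154361, 151124 and 200700 UMIs. Median UMIs per barcode ran from 26 in corn oil/cellulose mouse 1 to 528.5 in fish oil/pectin mouse 4. Haemoglobin genes took 18.4% ± 19.1 of UMIs in corn oil/cellulose and 32.8% ± 19.8 in fish oil/pectin mice (SD, n = 4 each), from 0.0086% in corn oil/cellulose mouse 3 to 54.3% in fish oil/pectin mouse 3 (two-sided exact permutation p = 0.286). Mitochondrially encoded genes took 18.0% ± 15.6 and 12.6% ± 9.11 of UMIs (SD, n = 4 each, exact permutation p = 0.486). None of 7 library measures passed the exact permutation test after Benjamini-Hochberg adjustment, and the smallest p that 4 mice against 4 can give is 0.0286. Shared droplet barcodes put corn oil/cellulose mice 1, 2 and 3 with fish oil/pectin mouse 1 in 1 pool of libraries (pool 1) and the other mice in another (pool 2), so each within-pool difference below rests on 1 mouse of one diet.

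Barcodes with at least 100 UMIs fell into epithelial-like, fibroblast-like, myeloid-like, adipocyte and mesothelial-like, haemoglobin-led and mixed classes. The epithelial-like class joined a goblet-like cluster of 194 barcodes, with 14 of 19 goblet markers raised and Muc2, Fer1l6, Bcas1 and Clca1 leading, and an absorptive colonocyte-like cluster of 540 barcodes, with 6 of 22 markers raised. That last name is weak, since no colonocyte marker stood among its 10 leading genes, which included Ybx2, Myb, Hao2 and Fam3d, and at a finer clustering resolution the matching cluster was named crypt base and stem-like from 6 of 17 markers. At that resolution another cluster of 184 barcodes, led by Reg3b, Car1 and Fabp6, had 11 of 22 colonocyte markers raised, and 170 of its barcodes lay in the mixed class here, where 8 of 22 were raised. Colonocyte RNA therefore also lies outside the epithelial-like class. Epithelial-like barcodes made up 30.7% ± 11.5 in corn oil/cellulose and 26.0% ± 34.4 in fish oil/pectin mice (SD, n = 4 each), and fish oil/pectin mouse 4 held 77.4% against 5.38% to 11.6% in the other fish oil/pectin mice. Haemoglobin-led barcodes, with the red cell genes Alas2 and Epb41 among their leading genes, made up 24.1% ± 20.2 and 39.9% ± 20.6 (SD, n = 4 each). Fibroblast-like barcodes, led by Pi16, C3 and Col3a1, made up 13.7% ± 17.5 and 6.77% ± 8.35 (SD, n = 4 each).

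**Figure D1:**
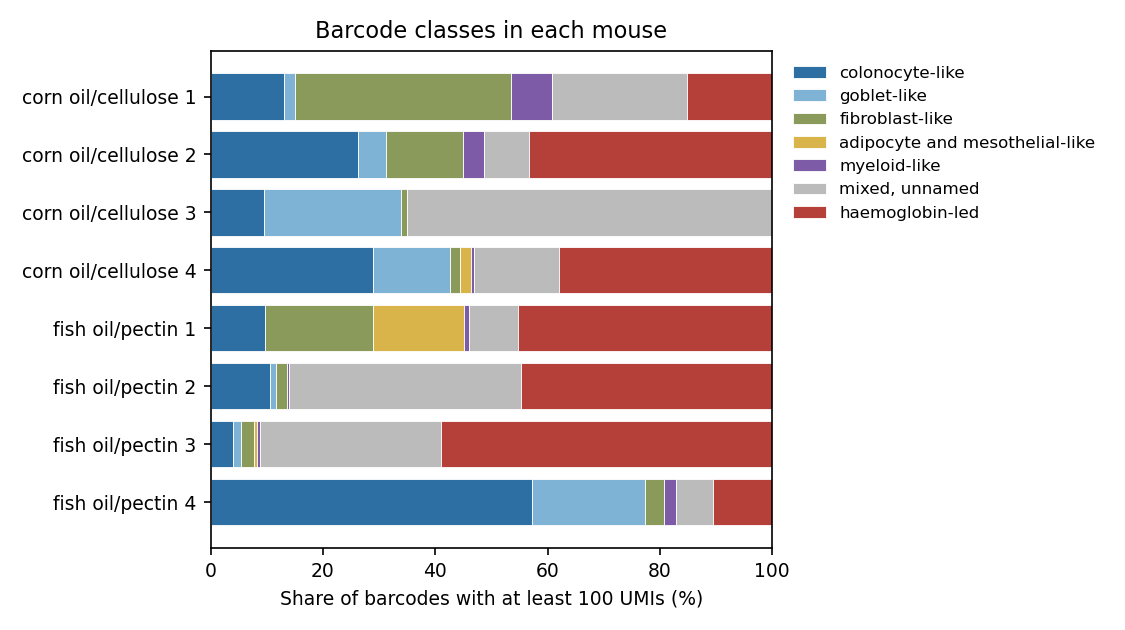
Share of barcodes with at least 100 UMIs (x axis, percent) in each class for each of the 8 mice (y axis, diet and mouse number). Haemoglobin-led barcodes range from 0% in corn oil/cellulose mouse 3 to 59.0% in fish oil/pectin mouse 3, and fish oil/pectin mouse 4 holds 77.4% epithelial-like barcodes.

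No class share passed an exact permutation test between diets (10 tests, adjusted p = 0.943 for each). The smallest p that 4 mice against 4 can give is 0.0286 before adjustment. No single class could therefore pass alone, and differences between diets are not excluded. The epithelial-like difference was -4.73 points (exact permutation p = 0.914), with -17.1 in pool 1 and -11.2 in pool 2. The haemoglobin-led difference was 15.8 points (exact permutation p = 0.257), with 25.7 in pool 1 and 0.157 in pool 2. The share of all UMIs from the 16 fixed cell type lists passed for none of them (adjusted p = 1.00 for each), and the same limit holds. The epithelial list stood at 2.48% ± 1.09 in corn oil/cellulose and 1.87% ± 1.28 in fish oil/pectin mice (SD, n = 4 each, exact permutation p = 0.514). The goblet list stood at 1.10% ± 0.637 and 0.763% ± 0.496 (SD, n = 4 each, exact permutation p = 0.457). The adipocyte and mesothelial list took 0.351% of UMIs in fish oil/pectin mouse 1 and at most 0.0338% in any other mouse.

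Counts summed over all barcodes of each mouse show the whole tissue section. Among the genes with the smallest p values, higher values in fish oil/pectin mice were seen for Scd1, the stearoyl-CoA desaturase (log2 fold change 3.24, SE 0.93), Clec2e, a C-type lectin (1.97, SE 0.62), and Fasn, the fatty acid synthase (1.95, SE 0.67). Others were Slc13a2, a sodium-coupled transporter of succinate and citrate (1.78, SE 0.48), Mapre3 (1.6, SE 0.59), Acss2, which makes acetyl-CoA from acetate (1.51, SE 0.54), Arhgef39 (1.48, SE 0.54) and Hadha, an enzyme of mitochondrial fatty acid oxidation (1.40, SE 0.49). Lower values were seen for Maff, a stress-induced transcription factor (-3.08, SE 0.74), Cep120 (-1.93, SE 0.66), Bcas1 (-1.86, SE 0.61) and Slc15a1, the peptide transporter PEPT1 (-1.86, SE 0.67). Hoxd10 (-1.65, SE 0.58), Slc11a2, the iron importer DMT1 (-1.6, SE 0.57), Cnpy2 (-1.55, SE 0.57) and Tdrd3 (-1.32, SE 0.48) followed. None of these passed the test. The quasi-likelihood test of edgeR called 0 of 4471 genes after Benjamini-Hochberg adjustment, and 108 had an unadjusted p under 0.05. The adjusted p was 0.999 for each gene named here (4 mice per diet).

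DESeq2 and limma voom also called 0 genes, with 139 and 198 at an unadjusted p under 0.05, and with the pool in the edgeR fit 0 were called, with 177. Within pools, Scd1 differed by 4.97 and 0.73, Fasn by 3.11 and 1.2, Slc13a2 by 1.55 and 1.92, Clec2e by 1.69 and 1.79, and Maff by -2.87 and -2.09 (log2, pools 1 and 2). Scd1 had 4, 1, 0 and 10 UMIs in corn oil/cellulose mice 1 to 4, and 25, 17, 2 and 16 in fish oil/pectin mice. In fish oil/pectin mouse 4, 14 of the 16 lay in 1 barcode, and the 2 of mouse 3 lay in 1 barcode. In fish oil/pectin mice 1 and 2 they lay in 13 barcodes each. Without the count filter 4 genes were called, Alb, Atf3, Reg3b and Scd1, and without fish oil/pectin mouse 4 there was 1, Reg3b. Reg3b was chosen after its values were seen, and its UMIs were 2, 0, 1 and 1 in corn oil/cellulose and 5, 91, 29 and 0 in fish oil/pectin mice. Those of Fabp6, an ileal gene also chosen afterwards, were 50, 0, 1 and 3, and 2, 107, 31 and 3.

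Gene lists in the all-cell sums gave 6 called of 25 tested by camera with a preset correlation of 0.01, 5 higher in fish oil/pectin mice and 1 lower. Fatty acid synthesis and desaturation rose, with a median log2 fold change of 1.51 over 9 tested genes, 9 of them above 0 and 4 that rose when adjusted over the list alone: Scd1, Fasn, Acss2 and Acaca, the acetyl-CoA carboxylase (2.07, SE 0.79). Its adjusted p was 1.04e-07, and 0.186 with an estimated correlation. The medians were 2.66 in pool 1, whose single fish oil/pectin mouse held the adipocyte genes, and 0.58 in pool 2. Without fish oil/pectin mouse 1 the median was 0.76 (camera adjusted p = 0.000488), without fish oil/pectin mouse 4 it was 2.30 (adjusted p = 2.93e-09), and without adipocyte-like barcodes it was 0.58 (adjusted p = 0.0243). With an estimated correlation these adjusted p were 0.316, 0.461 and 0.681.

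Fatty acid oxidation and PPAR targets rose by a median of 0.42, with 16 of 21 genes above 0 and 0 that rose when adjusted over the list alone (camera adjusted p = 0.00374, and adjusted p = 0.186 with an estimated correlation). Its members of smallest p were Hadha (1.40), Acadl (1.04, SE 0.45), the fatty acid binding protein Fabp2 (1.80, SE 0.89) and Acads (0.89, SE 0.51), and the list medians were 0.39 and 0.30 in pools 1 and 2. Haemoglobin-led barcodes held 36.0% of its UMIs, and its median was 0.51 without them (adjusted p = 0.000671), 0.22 without adipocyte-like barcodes (adjusted p = 0.0308) and 0.73 without fish oil/pectin mouse 4 (adjusted p = 0.0140). With an estimated correlation these adjusted p were 0.138, 0.681 and 0.461. Ketone and short-chain fatty acid handling rose by a median of 0.41 with 9 of 10 genes above 0 and 0 that rose when adjusted over the list alone, with Acss2 (1.51) and the lactate transporter chaperone Bsg (1.19, SE 0.63, but -1.91 and 1.12 in pools 1 and 2). Its camera adjusted p was 0.0191, and 0.568 with an estimated correlation. The medians were -1.38 and 0.62 in pools 1 and 2, and the adjusted p was 0.302 with the pool in the fit. It was 0.286 without corn oil/cellulose mouse 2, where the median was 0.24, 0.0566 without corn oil/cellulose mouse 4, 0.257 without fish oil/pectin mouse 2 and 0.176 without fish oil/pectin mouse 4. Without corn oil/cellulose mouse 1 the median was 1.04 (adjusted p = 0.00709, and 0.513 with an estimated correlation).

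The NRF2 and glutathione list, genes of antioxidant defence, rose by a median of 0.57 with 12 of 14 genes above 0 and 0 that rose when adjusted over the list alone (camera adjusted p = 0.000695, and adjusted p = 0.568 with an estimated correlation). Catalase (Cat, 2.16, SE 0.96), transketolase (Tkt, 1.33, SE 0.65), Aldh1a1 (1.79, SE 0.99) and Gpx1 (1.6, SE 1.03) had its smallest p values. Haemoglobin-led barcodes held 40.6% of the list's UMIs, and Cat, Aldh1a1 and Gpx1 were among the 20 leading genes of 1 haemoglobin-led cluster. Without those barcodes the list's median was 0.53 (adjusted p = 0.154) and Gpx1 was -0.71. With the pool in the fit the median was 0.36 (adjusted p = 0.250), and the within-pool medians were 0.38 and 0.22. The adjusted p was 0.0574 without corn oil/cellulose mouse 3 and 0.0608 without fish oil/pectin mouse 3. The median was 0.33 without fish oil/pectin mouse 2 and 0.99 without fish oil/pectin mouse 4.

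Oxidative phosphorylation rose by a median of 0.35 with 45 of 56 genes above 0 and 0 that rose when adjusted over the list alone (camera adjusted p = 0.00767, and adjusted p = 0.940 with an estimated correlation). The complex I genes Ndufs3 (0.99, SE 0.57), Ndufa2 (0.90, SE 0.53) and Ndufs1 (0.85, SE 0.57) lay above 0 and Uqcrc2 (-1.23, SE 0.69) below. The within-pool medians were -0.46 and 0.35, and the pool fit gave 0.18 (adjusted p = 0.627). The adjusted p was 0.586 without corn oil/cellulose mouse 2, 0.819 without fish oil/pectin mouse 2, where the median was -0.03, and 0.504 without fish oil/pectin mouse 3. With either corn oil/cellulose mouse 1 or fish oil/pectin mouse 4 left out the median was 0.56. Immediate early and heat shock genes fell by a median of 0.82 on the log2 scale, with 10 of 15 genes below 0 and 0 that fell when adjusted over the list alone (camera adjusted p = 0.00374, and adjusted p = 0.568 with an estimated correlation). Atf3 (-3.18, SE 1.29), Fos (-1.14, SE 0.55), Klf6 (-1.10, SE 0.50) and Dusp1 (-1.0, SE 0.50) led that list. Its medians were -1.26 and -0.58 in pools 1 and 2, and its adjusted p was 0.0554 without fish oil/pectin mouse 1. No list was called by camera with an estimated correlation (0 of 25, 2 at an unadjusted p under 0.05) or by fry (0 of 25, with 1), and with an estimated correlation none was called in any of the list alternatives.

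**Figure D2:**
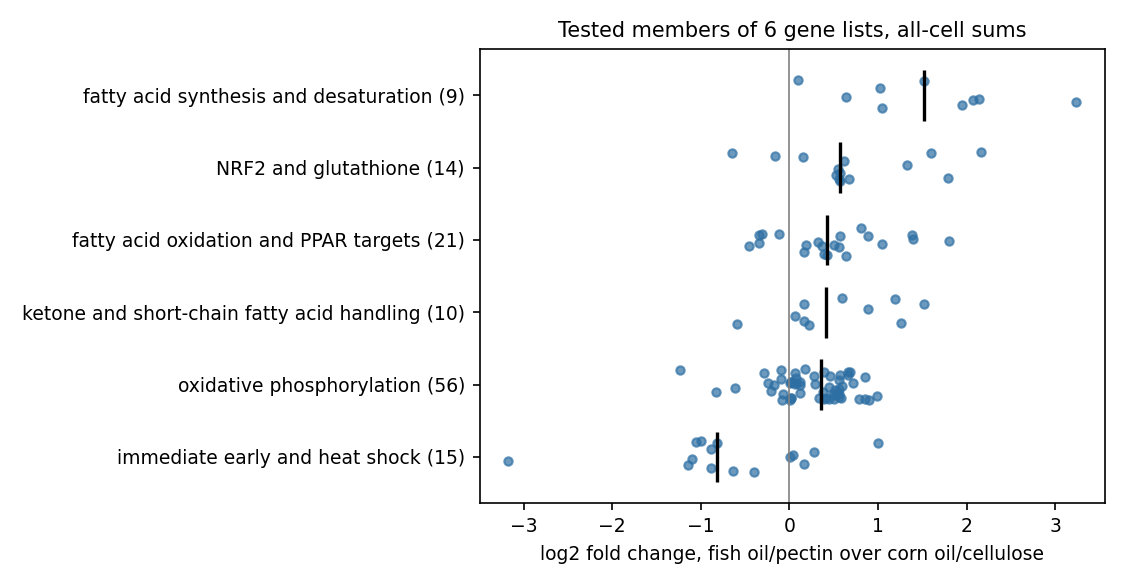
Log2 fold changes of fish oil/pectin over corn oil/cellulose mice (x axis) for the tested members of the 6 called gene lists in the all-cell sums (y axis, number of tested genes in parentheses). Each point is 1 gene and each black bar is the list's median, from 1.51 for fatty acid synthesis and desaturation to -0.82 for immediate early and heat shock genes.

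No difference between diets was detected in the all-cell sums for the lists closest to the series title. Only part of each could be tested: 11 of 25 ferroptosis suppressors, 13 of 31 drivers and 10 of 20 iron handling genes. Ferroptosis suppressors had a median of -0.14 and a mean of 0.18 over 11 tested genes, with camera pointing up (adjusted p = 0.992). In that list 4 genes were above 0 and 7 below, and 1, Scd1, rose when adjusted over the list alone (edgeR adjusted p = 0.0470). Slc40a1, the iron exporter ferroportin (-0.78, SE 0.46), Mboat1 (-0.58, SE 0.58) and Gclm (0.56, SE 0.66) came next. Ferroptosis drivers had a median of 0.13 over 13 genes, 7 above 0 and 6 below (camera adjusted p = 0.493). Among them were Ncoa4, the receptor for ferritin breakdown (1.68, SE 0.91), and Cyb5r1 (1.39, SE 0.73). The glutamine transporter Slc1a5 was at 1.22 (SE 0.68, with 2.82 and -0.24 in pools 1 and 2). The list as fixed also held Acsl3 (-0.80, SE 0.56), whose place among drivers was not checked and should not be read as its role. Iron handling had a median of 0.11 over 10 genes (adjusted p = 0.992), with Slc11a2 (-1.6) and the mitochondrial iron importer Slc25a37 (1.84, SE 0.98). Ncoa4 and Slc25a37 were both among the 20 leading genes of a haemoglobin-led cluster. Over the alternatives Ncoa4 ranged from 0.28 to 2.35 and Slc25a37 from 0.40 to 2.38. Medians in pools 1 and 2 were -0.60 and 0.02 for suppressors, -0.19 and -0.03 for drivers, and -1.46 and -0.11 for iron handling.

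Of single genes fixed in advance, Gpx4 was not analysed here. Slc7a11, the cystine importer, had 1 UMI among all 8 libraries, Acsl4 18 (13 of them in corn oil/cellulose mouse 1), Aifm2 31, Pdk4 10, Lgr5 4 and Mki67 13. None of these was tested, so a diet difference in them was not detectable at this depth. In the all-cell sums Car1, a carbonic anhydrase of colonocytes, was at 1.84 (SE 0.99), Muc2, the main mucin of goblet cells, at -0.48 (SE 0.95), and Cpt1a at 0.19 (SE 0.51). Tfrc, the transferrin receptor, was at 0.13 (SE 0.57), Slc26a3 at -0.12 (SE 0.72) and Fth1, the ferritin heavy chain, at -0.07 (SE 0.66). All had an edgeR adjusted p of 0.999. Within pools Car1 differed by 0.67 and 2.43, Fth1 by -1.88 and -0.31, and Tfrc by -2.17 and 0.77 (log2, pools 1 and 2).

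In the epithelial-like class, Slc13a2 (ENSMUSG00000001095) was higher in fish oil/pectin mice. Its log2 fold change was 2.83 (SE 0.56, edgeR adjusted p = 0.000249), from 0, 2, 6 and 12 UMIs in corn oil/cellulose and 5, 8, 6 and 61 in fish oil/pectin mice. Per 1000000 UMIs of that class it stood at 78.9 ± 60.4 and 1159 ± 836 (SD, n = 4 each), and all 4 fish oil/pectin mice lay above all 4 corn oil/cellulose mice. The exact permutation p was 0.0286, the smallest possible (0.0571 after adjustment over 10 measures of this gene). The class held 5351, 26200, 41121 and 128768 UMIs in corn oil/cellulose mice 1 to 4, and 2142, 8853, 5794 and 167900 in fish oil/pectin mice 1 to 4. Slc13a2 per 1000000 was 0, 76.3, 146 and 93.2, and 2334, 904, 1036 and 363, in that order. The upper Poisson bound of corn oil/cellulose mouse 1 was 689, above the 363 of fish oil/pectin mouse 4, so the separation of the diets is not firm. The difference between diets was 4.16 in pool 1 and 2.56 in pool 2 (log2), and 3.14 (SE 0.67, edgeR adjusted p = 0.00149) with the pool in the fit. The class held unequal parts of the epithelial RNA: of the epithelial-list UMIs in barcodes of at least 100 UMIs it took 130 of 482, 746 of 941, 2112 of 2593 and 7255 of 8518 in corn oil/cellulose mice 1 to 4. In fish oil/pectin mice 1 to 4 it took 37 of 160, 286 of 2360, 338 of 963 and 6381 of 6793. Slc13a2 lies on the minus strand of chromosome 11, from 78397087 to 78422217, in the reference annotation of GRCm38.

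The Slc13a2 call rests on few molecules and on a class whose naming rule was settled after a first epithelial test of diet, which also called Slc13a2, had been seen. Its edgeR adjusted p ranged from 0.000160 to 0.653 over 25 alternatives, of which 17 kept the call. In 4 more it was filtered out before testing: a minimum count of 10, thinning, Scrublet-called barcodes removed and the colonocyte-like cluster alone. It was 0.0840 without corn oil/cellulose mouse 2, 0.268 without corn oil/cellulose mouse 3, and 0.288 without corn oil/cellulose mouse 4. It was also 0.0615 without fish oil/pectin mouse 1, 0.0818 without fish oil/pectin mouse 2, 0.0664 without fish oil/pectin mouse 3, 0.653 without the count filter and 0.230 with the goblet-like share in the fit. In the colonocyte-like cluster alone Slc13a2 had 9 UMIs in corn oil/cellulose and 57 in fish oil/pectin mice, 58.2 ± 67.4 and 1248 ± 806 per 1000000 UMIs (SD, n = 4 each, exact permutation p = 0.0286). In other barcodes of at least 100 UMIs it stood at 40.7 ± 47.7 and 88.0 ± 65.1 per 1000000 (SD, n = 4 each, exact permutation p = 0.314).

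**Figure D3:**
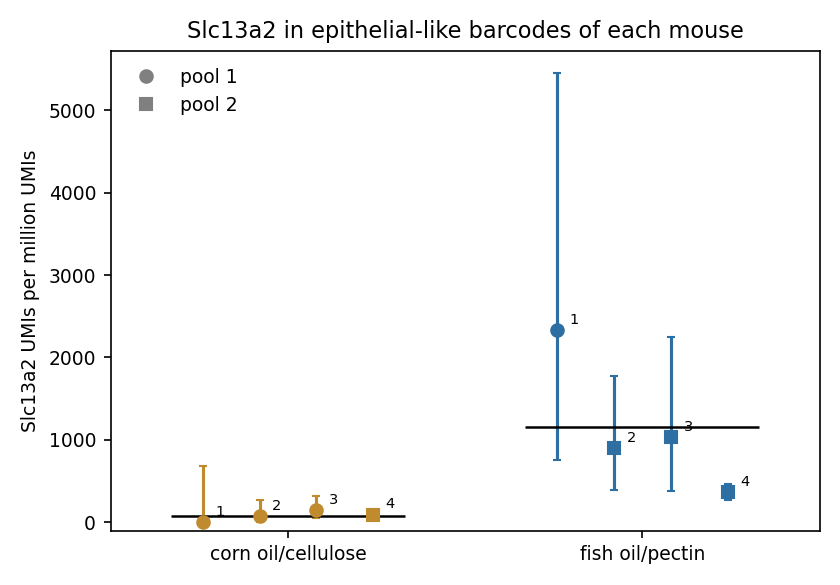
Slc13a2 UMIs per 1000000 UMIs of epithelial-like barcodes (y axis) in each mouse of the 2 diets (x axis), with 95% Poisson intervals, mouse numbers beside the points, circles for pool 1 and squares for pool 2. Black lines are the means, 78.9 in corn oil/cellulose and 1159 in fish oil/pectin mice, and all 4 fish oil/pectin mice lie above all 4 corn oil/cellulose mice.

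Other epithelial-like genes gave values without passing the test. Those of smallest p above 0 were Car1 (1.96, SE 0.56, edgeR adjusted p = 0.115), Ubxn1 (1.46, SE 0.62), Cystm1 (1.45, SE 0.53), Clec2d (1.32, SE 0.57), Slc4a2, an anion exchanger (1.24, SE 0.54), Snrnp70 (1.14, SE 0.52) and Clasrp (1.08, SE 0.50). Those below 0 were S100a6 (-1.81, SE 0.62), Serpinb1a (-1.70, SE 0.61), Fhl1 (-1.64, SE 0.65), Slc15a1 (-1.61, SE 0.58), Bcas1 (-1.56, SE 0.60), the trypsin inhibitor Spink1 (-1.52, SE 0.55), the galectin Lgals3 (-1.52, SE 0.62) and Adh1, an alcohol dehydrogenase (-1.29, SE 0.52). Fth1 was at -0.58 (SE 0.54), Muc2 at -0.33 (SE 0.70) and Slc26a3 at 0.03 (SE 0.59). Of 559 tested genes, 30 had an unadjusted p under 0.05 and Slc13a2 alone was called. Slc4a2 (-2.69 and 0.92), Clasrp (-1.85 and 0.98) and Fth1 (0.75 and -1.66) turned sign between pools 1 and 2. Car1 differed by 2.42 and 1.70, and without fish oil/pectin mouse 4 Car1 (2.82, adjusted p = 0.000336) and Adh1 (-3.77, adjusted p = 0.0308) were called too. Clec2e, chosen after its values were seen, was called without corn oil/cellulose mouse 1, where 3 genes were called, and without fish oil/pectin mouse 3, where it was the only 1. Its UMIs in this class were 2, 1, 0 and 5 in corn oil/cellulose and 1, 2, 0 and 67 in fish oil/pectin mice, so mouse 4 held nearly all.

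Gene lists in the epithelial-like sums gave 0 called of 9 by camera, 2 at an unadjusted p under 0.05. With an estimated correlation and by fry 0 were called (0 at an unadjusted p under 0.05 for each). The 9 held no ferroptosis, iron handling, NRF2 and glutathione or fatty acid list, since too few of their genes passed the count filter. A diet difference in those lists was therefore not tested by camera in this class. The absorptive colonocyte list had a median of 0.21, with 8 of 11 genes above 0 and 1, Car1, that rose when adjusted over the list alone (camera adjusted p = 0.0745, and 0.726 with an estimated correlation). Ceacam1 (1.11, SE 0.58), Aqp8 (0.55, SE 0.51) and Cdhr5 (-0.48, SE 0.54) followed, and the medians were -0.26 and 0.02 in pools 1 and 2. Immediate early and heat shock genes had a median of -0.76, with 6 of 6 genes below 0 (camera adjusted p = 0.0745), among them Fos (-1.02, SE 0.60), Klf6 (-0.90, SE 0.57), Jund (-0.79, SE 0.59) and Btg2 (-0.73, SE 0.54, with -1.0 and 0.55 in pools 1 and 2), and medians of -2.90 and -0.16 within pools. With the pool in the fit camera called 2 lists, both lower in fish oil/pectin mice: goblet markers at a median of -0.87 and antimicrobial and barrier genes at -0.86 (adjusted p = 0.0323 for both, and 0.750 with an estimated correlation). The cell mix differed too: in pool 1 goblet-like barcodes held 17.1%, 30.9% and 85.6% of the class UMIs in corn oil/cellulose mice 1 to 3 and 0 in fish oil/pectin mouse 1, and the medians within pools 1 and 2 were -3.53 and -0.59 for goblet markers and -3.29 and -0.44 for antimicrobial genes. Leaving out single mice gave between 1 and 3 called lists: 1 without each of corn oil/cellulose mice 1, 2, 3 and 4 and fish oil/pectin mice 3 and 4, 2 without fish oil/pectin mouse 1 and 3 without fish oil/pectin mouse 2.

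Whether the diet difference itself differed between epithelial-like and other barcodes was tested with the mouse as a block, and edgeR called 0 of 2084 genes (43 at an unadjusted p under 0.05). For Slc13a2 the difference between classes was 0.63 (log2, SE 1.2, adjusted p = 1.00). Haemoglobin-led barcodes of 3 corn oil/cellulose and 4 fish oil/pectin mice gave 0 called of 132 genes by edgeR (10 at an unadjusted p under 0.05), with Hba-a1 at -1.02 (SE 0.36) and Pabpc1 at -0.78 (SE 0.28). The mixed cluster, in which 9 of 14 smooth muscle and 8 of 22 colonocyte markers were raised, gave 0 of 275 (16 at an unadjusted p under 0.05). Fibroblast-like, myeloid-like and adipocyte and mesothelial-like barcodes reached 10 per mouse in too few mice to compare the diets.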

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

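The tests of explanations in this part were chosen after the results were seen, and the bounds for reading them were rewritten after that. A value is listed here when 1 mouse of a group of 4 stood apart, its gap to the nearest mouse taking most of the group's range; 20 of 182 groups did so where chance gives about 9.1.

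Slc13a2 was higher in epithelial-like barcodes of fish oil/pectin mice by a log2 fold change of 2.83 (SE 0.56). With the pool in the fit it was 3.14 (SE 0.67), and the differences within pools 1 and 2 were 4.16 and 2.56. These argue against an equal shift of all mice in a pool as the whole cause. Each within-pool difference rests on 1 mouse of one diet, in pool 1 on a mouse with 5 Slc13a2 UMIs. A part played by the pool therefore cannot be told apart from the diet. A smaller goblet-like part of the sums is argued against as the whole cause, but only by the rewritten bound. Under the earlier bound it had been open. In the colonocyte-like cluster alone all 4 fish oil/pectin mice lay above all 4 corn oil/cellulose mice. The difference there was 1190 per 1000000 UMIs (SE 404). That rests on 0, 2, 0 and 7 UMIs in corn oil/cellulose and 5, 7, 5 and 40 in fish oil/pectin mice. With the goblet-like share in the fit the log2 fold change was 2.50 (SE 0.71), a lower fold with a larger SE, and the call ended (edgeR adjusted p = 0.230). The choice of barcodes by the clustering cannot be told apart from the diet: over all barcodes the exact permutation p was 0.0286 per 1000 UMIs of the epithelial list (2.63 ± 1.14 and 13.1 ± 9.84, SD, n = 4 each, 0.0571 adjusted) and 0.0857 per 1000000 UMIs, and in barcodes of at least 100 UMIs 0.0571 on both scales. Chance cannot be excluded, since 8 of the 35 splits of the mice into equal groups called at least 1 gene, the highest other split called 3 and the split by pool 2. An effect of the diet stays open as an untested hypothesis.

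Fatty acid synthesis genes were higher in the all-cell sums of fish oil/pectin mice, with a median log2 fold change of 1.51. Adipocyte-like cells in the section could account for part, since the median was 0.58 without adipocyte-like barcodes, where camera's adjusted p was 0.0243 (0.681 with an estimated correlation). Whether they account for all of it cannot be told apart from the diet, since without these and the 19 colonocyte-like and 8 unnamed barcodes that join them at the finer clustering resolution it was 0.60 (adjusted p = 0.0276, and 0.679 with an estimated correlation), and without fish oil/pectin mouse 1 as well it was 0.53 (adjusted p = 0.0892). With the pool in the fit the median was 1.98 (camera adjusted p = 5.45e-11, and with an estimated correlation 0.159, or 0.00635 unadjusted). The medians were 2.66 and 0.58 within pools 1 and 2. Both lie above 0, but each rests on 1 mouse of one diet, in pool 1 on the mouse that held the adipocyte genes. A pool difference therefore cannot be told apart from the diet. Chance cannot be excluded for the count of lists: 18 of 35 splits called at least the 6 lists of the real one, the highest other split called 14 and the split by pool called 7, and with an estimated correlation 0 were called.

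NRF2 and glutathione genes and oxidative phosphorylation genes were both higher in the all-cell sums of fish oil/pectin mice (medians 0.57 and 0.35). RNA of haemoglobin-led barcodes cannot be told apart from the diet for either list. Without those barcodes the median of oxidative phosphorylation was 0.38, which camera called at the preset correlation (adjusted p = 0.00432) but not with an estimated one (adjusted p = 0.931), and that of the NRF2 list was 0.53 with the call ended (adjusted p = 0.154) and fewer genes tested. A pool difference cannot be told apart from diet for either list, since with the pool in the fit the medians were 0.36 (adjusted p = 0.250) and 0.18 (adjusted p = 0.627) and pool and diet are partly confounded. A biological effect of the diet stays open and untested.

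For the other counts the real value was 0, so 35 of 35 splits reach it by construction and nothing about chance is decided. The all-cell sums had 0 called genes by edgeR, the highest other split 135 and the split by pool 0. That highest split set corn oil/cellulose mouse 1 with fish oil/pectin mice 1, 2 and 3, and what these mice share was not tested. Lists in the epithelial-like sums had 0 by camera, the highest other split 7 and the split by pool 5. The interaction had 0 and the highest other split 2, haemoglobin-led barcodes 0 and 6, and the mixed cluster 0 and 10.

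Corn oil/cellulose mouse 1 held 5180 barcodes, where the other mice on that diet held 106 to 527. Fish oil/pectin mouse 4 had a median of 528.5 UMIs and 394.5 genes per barcode, where the others had 93 to 128 UMIs and 27 to 50 genes. Fish oil/pectin mouse 4 also held 77.4% epithelial-like barcodes (5.38% to 11.6% in the others), 20.2% goblet-like (0% to 1.39%) and 57.2% colonocyte-like barcodes (3.98% to 10.5%). Fish oil/pectin mouse 1 held 35.6% stromal-like barcodes (2.01% to 3.42% in the others), 19.3% fibroblast-like (2.01% to 3.42%) and 0.351% of UMIs from the adipocyte and mesothelial list (0.000997% to 0.0168%).

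In the all-cell sums, in counts per 1000000 after scaling by TMM factors and with the range of the other mice on the diet, fish oil/pectin mouse 1 had Scd1 at 734 (44.5 to 161), Slc1a5 at 1821 (218 to 445) and Muc2 at 822 (3205 to 3558). Corn oil/cellulose mouse 1 had Car1 at 1676 (231 to 456) and Clec2e at 89.4 (11.0 to 23.4), and corn oil/cellulose mouse 3 had Atf3 at 1448 (44.7 to 110). Fish oil/pectin mouse 3 had Cyb5r1 at 222 (26.2 to 58.7), and fish oil/pectin mouse 4 had Acsl3 at 229 (66.7 to 88.1). In the epithelial-like sums, fish oil/pectin mouse 2 had Ubxn1 at 2383 (793 to 869), corn oil/cellulose mouse 2 had Cdhr5 at 1448 (2934 to 3133), and fish oil/pectin mouse 4 had Fos at 518 (1589 to 1739).
 The TMM factors of the all-cell sums ran from 0.314 in fish oil/pectin mouse 3 to 1.82 in fish oil/pectin mouse 4. Without them Scd1 (888, others 14.0 to 125) and Atf3 (1968, others 49.6 to 116) alone of these genes still stood apart, and Muc2 was 995 against 1118 to 5846.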

How the results depend on the processing

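Of the alternatives below, those with the pool, the goblet-like share, haemoglobin-led or adipocyte-like barcodes, haemoglobin and mitochondrially encoded genes, the colonocyte-like cluster alone, the single-precision clustering and the seeds were added after the data were seen. In the all-cell sums, named genes kept their direction and their side of the threshold in 365 of 376 values with 1 mouse left out and in 633 of 645 others. In the epithelial-like sums they did so in 153 of 165 and 438 of 460. Lists in the all-cell sums did so in 51 of 72 and 54 of 88. No gene had a call to lose in the all-cell sums, and Slc13a2 in the epithelial-like sums lost its call in 6 of 8 fits with 1 mouse left out. Few small changes could be found: in simulated all-cell sums 3.14% of genes changed by a fold of 2 were recovered. Whether depth or the spread between mice sets that limit was not tested. Leaving TMM factors out moved the median log2 fold change of all genes by -0.18 in the all-cell sums and by 0.14 in the epithelial-like sums, so values near 0 can turn by scaling alone. The goblet-like cluster alone and naming by the top 20 genes were not run, since too few mice held 10 such barcodes. For the changes below the cause was not tested, beyond the fewer genes or mice that some alternatives hold by construction.

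Counts of called genes moved as follows. The all-cell sums had 4 without the count filter, and between 0 and 1 with single mice left out. The epithelial-like sums, with 1 called gene, had 2 without TMM factors, 4 at the finer clustering resolution, 3 with barcodes assigned by marker UMIs and 3 with the single-precision clustering. They had 0 with a minimum count of 10, 0 without the count filter, 0 after thinning, 0 without Scrublet-called barcodes, 0 in the colonocyte-like cluster alone and 0 with the goblet-like share as a covariate, and between 0 and 3 with single mice left out. Slc13a2 was filtered out before testing with the minimum count of 10, after thinning, without Scrublet-called barcodes and in the colonocyte-like cluster alone. Called lists in the all-cell sums, 6 of 25, were 3 with barcodes of at least 100 UMIs, 0 with an estimated correlation and 0 by fry. In the epithelial-like sums they were 2 with the pool as a covariate, 1 in the colonocyte-like cluster alone, and between 1 and 3 with single mice left out.

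Of the 6 called lists, ketone handling (adjusted p = 0.244) and oxidative phosphorylation (adjusted p = 0.0809) lost their calls without the count filter, and immediate early genes (adjusted p = 0.0798) with barcodes of at least 100 UMIs, where fatty acid synthesis and ketone handling were not tested, since fewer than 5 of their genes passed the count filter. Leaving out single mice, the median of oxidative phosphorylation ranged from -0.028 without fish oil/pectin mouse 2 to 0.56 without fish oil/pectin mouse 4.

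Class shares, as differences in points, turned sign as follows. Epithelial-like barcodes stood at 11.0 without Scrublet-called barcodes, and between -21.9 and 2.14 with single mice left out. Haemoglobin-led barcodes stood at -5.46 without Scrublet-called barcodes. Scrublet called 51.9% of barcodes in corn oil/cellulose mouse 2 and 57.7% in corn oil/cellulose mouse 4 but 0 in fish oil/pectin mice 2 and 3. Stromal-like barcodes stood at 3.67 with at least 50 UMIs, at 1.14 by marker UMIs, and between -11.4 and 4.84 with single mice left out. Unnamed barcodes stood at 8.41 by marker UMIs, and between -12.5 and 6.53 with single mice left out. The cluster named colonocyte-like at the finer resolution is another set of barcodes, with a difference of -2.64. Colonocyte-like barcodes stood between -11.3 and 6.40 with single mice left out. Fibroblast-like barcodes ranged from -11.2 to 1.30, and the UMI share of the adipocyte and mesothelial list from -0.00802 to 0.109.

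Among library measures, with barcodes of at least 100 UMIs the difference in barcodes was 30 and in UMIs 772. With single mice left out the difference in barcodes ranged from -1470 to 221, in UMIs from -44261 to 13756, and in the percentage of mitochondrially encoded UMIs from -10.5 to 0.784.

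Lists near 0 turned in their median or their test. For ferroptosis suppressors the medians were -0.081 with barcodes of at least 100 UMIs, -0.17 without haemoglobin and mitochondrially encoded genes, -0.19 without haemoglobin-led barcodes, -0.14 without adipocyte-like barcodes, -0.15 without those of either clustering resolution and -0.14 by fry, whose tests pointed down, and from -0.21 to 0.053 with single mice left out. Ferroptosis drivers stood at -0.061 without the count filter and -0.041 with barcodes of at least 100 UMIs, and from -0.084 to 0.096 with single mice left out. Iron handling stood at -0.049 with the mouse number as a block, -0.050 without the count filter, -0.037 with barcodes of at least 100 UMIs, -0.34 with the pool as a covariate, -0.18 without haemoglobin and mitochondrially encoded genes and -0.074 without haemoglobin-led barcodes. By fry its median of 0.11 had a test pointing down, and with single mice left out it ranged from -0.065 to 0.30. In the epithelial-like sums, absorptive colonocyte markers stood at -0.14 with the pool as a covariate, and from -0.31 to 0.56 with single mice left out. Antimicrobial genes stood at -0.00047 in the colonocyte-like cluster alone, where the test pointed up. Goblet markers ranged from -0.75 to 0.54.

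Genes near 0 turned in the all-cell sums. Muc2 stood at 0.14 with the epithelial share as a covariate, and from -0.81 to 0.23 with single mice left out. Cpt1a stood at -0.36 with the pool as a covariate and -0.0097 with barcodes of at least 50 genes, and from -0.065 to 0.66. Without TMM factors Tfrc stood at -0.086, Slc26a3 at 0.0015 and Gclm at -0.019. With single mice left out Tfrc ranged from -0.12 to 0.61 and Slc26a3 from -0.97 to 0.23. Fth1 stood at 0.0097 with a minimum count of 10, 0.083 after thinning and 0.053 with barcodes of at least 100 UMIs, and from -0.90 to 0.21 with single mice left out. Gpx1 stood at -0.71 without haemoglobin-led barcodes.

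In the epithelial-like sums, with the goblet-like share as a covariate, Fth1 stood at 0.26 and Muc2 at 0.50, and Muc2 ranged from -0.83 to 0.64 with single mice left out. Slc26a3, at 0.03, stood at -0.044 with the mouse number as a block, though the numbers do not pair the mice, -0.028 by DESeq2, -0.0096 with TMMwsp, -0.51 without the count filter and -0.040 without genes over 1% of UMIs. It stood at -0.21 with the pool as a covariate, -0.27 at the finer resolution, -0.13 by marker UMIs and -0.15 with the single-precision clustering. With seeds 2 to 5 it stood at -0.081, -0.052, -0.051 and -0.053, and with single mice left out from -0.49 to 0.36. Aqp8 stood at -0.023 without the count filter and -0.22 with the pool as a covariate.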

Other observations

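The comparisons of list sums, the ileal and liver lists and the fit with the pool were chosen only after the data had been seen. Inside the epithelial-like barcodes, 2 fatty acid lists had higher values in fish oil/pectin mice when each list's UMIs were summed per mouse, without passing after adjustment, with haemoglobin and mitochondrially encoded genes left out. Fatty acid oxidation and PPAR target genes took 32.7 ± 5.38 of 10000 UMIs in corn oil/cellulose and 43.6 ± 1.90 in fish oil/pectin mice (SD, n = 4 each), and all 4 fish oil/pectin mice lay above all 4 corn oil/cellulose mice. The exact permutation p was 0.0286, the smallest possible, and 0.286 after adjustment over 20 lists; the differences were 11.7 in pool 1 and 8.70 in pool 2. Fatty acid synthesis genes took 8.84 ± 2.68 and 21.0 ± 12 (SD, n = 4 each), again with all 4 above all 4 (exact permutation p = 0.0286, adjusted 0.286), and differed by 30.2 in pool 1 and 5.67 in pool 2. That separation was narrow: fish oil/pectin mouse 2 had 12.8 from 10 UMIs and corn oil/cellulose mouse 1 had 12.4 from 6. The oxidation values of corn oil/cellulose mouse 1 (24.8) and fish oil/pectin mouse 1 (43.7) came from 12 and 9 UMIs. In the colonocyte-like cluster alone oxidation genes took 33.0 ± 8.69 and 47.1 ± 4.15 (SD, n = 4 each, exact permutation p = 0.0286, adjusted 0.429). Synthesis genes took 9.45 ± 3.70 and 22.9 ± 11.2 there, with 3 of 4 fish oil/pectin mice above all corn oil/cellulose mice (SD, n = 4 each, exact permutation p = 0.0571, adjusted 0.429). In fish oil/pectin mouse 1 the synthesis value was 38.8 from 8 UMIs, against 12.8, 15.4 and 17.0 in mice 2, 3 and 4, and without mouse 1 the difference was 6.22 in place of 12.2. That mouse also held the most adipocyte and mesothelial list UMIs (0.351%), and 3 of its 13 epithelial-like barcodes, all colonocyte-like, fell in the adipocyte-like cluster at the finer clustering resolution, as did 19 colonocyte-like barcodes over all mice. Without such barcodes the synthesis value of mouse 1 was 47.9, but its oxidation value was 35.9 in place of 43.7, where the highest corn oil/cellulose mouse had 35.6, and the pool 1 difference of oxidation genes was 3.93 in place of 11.7. Other lipid lists stood at 13.7 ± 2.30 and 15 ± 7.56 for sterol synthesis (SD, n = 4 each, exact permutation p = 0.743) and at 9.27 ± 2.60 and 10.2 ± 5.26 for eicosanoid enzymes (SD, n = 4 each, exact permutation p = 0.8). NRF2 and glutathione genes took 16.8 ± 3.91 and 25.9 ± 8.73 (SD, n = 4 each, exact permutation p = 0.114), ferroptosis drivers 22.4 ± 7.59 and 35.3 ± 13.1 (exact permutation p = 0.143), and ferroptosis suppressors 34.8 ± 13.4 and 29.8 ± 7.5 (exact permutation p = 0.600). The drivers differed by 33.0 in pool 1 and 1.13 in pool 2, with 53.4, 35.9, 28.9 and 23.1 in fish oil/pectin mice 1 to 4.

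Epithelial-like and other barcodes of the same mouse were also compared, and the outcome depended on the genes counted. With haemoglobin and mitochondrially encoded genes left out no list passed after adjustment. Over the UMIs of all genes 11 of 21 did, each higher in epithelial-like barcodes. The other barcodes included haemoglobin-led clusters with median haemoglobin shares from 84.2% to 90.4%. Over all genes that lowers the share of other lists there by construction. With haemoglobin and mitochondrially encoded genes left out, NRF2 and glutathione genes took 21.3 ± 7.93 of 10000 UMIs in epithelial-like barcodes (SD, n = 8). They took 70.9 ± 43.5 in other barcodes of at least 100 UMIs (SD, n = 8), and were lower in epithelial-like barcodes in 8 of 8 mice. Ferroptosis drivers took 28.8 ± 12.1 and 41.4 ± 16.9 (SD, n = 8), also lower in 8 of 8, but over all genes 26.7 ± 11.8 and 17.9 ± 8.36 (SD, n = 8), higher in 7 of 8 (exact sign-flip permutation p = 0.0469, adjusted 0.0656). With the genes left out, both had an exact sign-flip permutation p of 0.00781, the smallest possible with 256 assignments, and 0.0625 after adjustment over 20 lists. Fatty acid oxidation genes took 38.2 ± 6.91 and 103 ± 59.6 (SD, n = 8), lower in 7 of 8 mice (exact sign-flip permutation p = 0.0156, adjusted 0.0625). Iron handling genes took 17.0 ± 2.79 and 66.1 ± 48.1, xenobiotic response genes 48.2 ± 21.9 and 23.8 ± 11.5, and ferroptosis suppressors 32.3 ± 10.4 and 32.0 ± 10.2 (SD, n = 8). Over all genes suppressors took 29.7 ± 9.30 and 14.3 ± 5.18 (SD, n = 8, exact sign-flip permutation p = 0.00781, adjusted 0.0205), NRF2 genes 19.7 ± 7.30 and 27.0 ± 9.04 (SD, n = 8, lower in 6 of 8) and fatty acid oxidation genes 35.2 ± 6.90 and 38.8 ± 11.5 (SD, n = 8, lower in 4 of 8). By class and with the same genes left out, ferroptosis drivers took 106 of 10000 UMIs in adipocyte and mesothelial-like, 106 in haemoglobin-led, 27.1 in colonocyte-like and 22.9 in goblet-like barcodes. Suppressors took 46.2, 37.4, 35.7 and 38.9 in these classes in that order. The mice were unevenly spread over the classes: of 34 adipocyte and mesothelial-like barcodes, fish oil/pectin mouse 1 gave 22 and corn oil/cellulose mouse 4 gave 10. Of all genes' UMIs in haemoglobin-led barcodes, drivers took 12.9 of 10000 and suppressors 4.57.

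Transcripts of other organs or gut segments were unevenly spread over the libraries. Fabp6, a bile acid binding protein of the ileum, had 50 UMIs in corn oil/cellulose mouse 1, 107 in fish oil/pectin mouse 2 and 31 in fish oil/pectin mouse 3, and at most 3 in any other library. A list of ileal enterocyte genes took 0.189% of UMIs in fish oil/pectin mouse 2. Alb, the liver's albumin gene, had 119 UMIs in fish oil/pectin mouse 4, 86 of them in 1 barcode, and a list of liver genes took 0.0952% of that library's UMIs.

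With the pool in the fit, camera called lists in the all-cell sums that had not passed without it: antimicrobial and barrier genes at a median of -1.06 (adjusted p = 0.00627), epithelial markers at -0.77 (adjusted p = 0.0102), glycolysis at -0.61 (adjusted p = 0.0320) and fibroblast markers at 1.0 (adjusted p = 0.00627). With an estimated correlation none of the 25 lists was called in that fit, and the adjusted p was 0.637, 0.650, 0.637 and 0.637 for these 4. Medians within pools 1 and 2 were -1.68 and -0.32, -1.39 and -0.02, -1.80 and -0.65, and 1.34 and 0.99 for these lists in that order. Other lists without a call had, in the fit without the pool, medians of -0.51 for eicosanoid enzymes, -0.32 for apoptosis, 0.19 for sterol synthesis and 0.49 for mitochondrially encoded genes. In several lists without a call the median and camera's direction differed: crypt base and stem markers (-0.06, up), absorptive colonocyte markers (-0.01, up), fibroblast markers (-0.24, up) and goblet markers (0.06, down). For unfolded protein response genes the median (0.09) and camera's direction were up and the mean was -0.23.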
